A study of Mus musculus with 8 samples.

How the data were processed

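Total RNA from mouse splenic T cells was labelled with Cy3 and hybridised to one-colour Agilent oligonucleotide arrays, 1 sample per array. The 8 arrays form 4 groups of 2, read from the labels: wild-type cells in medium, Lsp1-deficient (KO) cells in medium, and both genotypes after 6 h with antibodies against CD3 and CD28. Per the labels' protocols, KO mice were backcrossed onto C57BL/6 for 10 generations, mice were 8 to 12 weeks old and matched for age and sex, and every RNA integrity number exceeded 9.5. How T cells were separated from other spleen cells is not given in the sources used here.

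The values are spot intensities on a linear scale, written by Agilent Feature Extraction 10.7.1.1 per the file headers, and the processed signal is the intensity after that program's background subtraction. Each array holds 62976 spots, of which 3671 are controls, and 55681 different non-control probes. The 8 arrays share 1 slide and 1 scan, so neither could be tested as a batch. On the slide, the stimulated and the medium arrays lie in different positions by row and the genotypes by column, so position and group cannot be told apart. The series' deposited value table holds the scanner's median intensity, with 0 values differing from it, on the linear scale and without centring.

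The analysed value was log2 of the processed signal minus its 75th percentile over the non-control probes of that array. Control spots and spots marked as outliers were left out, and repeated spots of a probe were averaged. Probes were kept when well above background on both arrays of at least 1 group, which left 37255. Between 58.4% and 69.2% of probes were well above background on an array, the 75th percentile of signal lay between 1200 and 1469, between 120 and 195 spots per array were marked as outliers, and 1 spot was saturated. The number of arrays limits the precision.

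Probe names came from the accessions in the files, matched without versions to a RefSeq table of the assembly GRCm38.p6. The file headers name the build mm9, so no coordinates from that table were used, only names and the order of neighbouring genes. Of the probes, 26056 were named and 29625 were not named here. Each gene symbol was represented by its probe with the highest mean over all arrays, giving 15138 genes. Another probe past the filter existed for 3846 of them. No gene called in any comparison had another probe called in the opposite direction.

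Genes were tested with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 and data.table version 1.17.8. A mean was fitted for each of the 4 groups over all 8 arrays, leaving 4 residual degrees of freedom, to which the moderated variance added 2.11. The 5 contrasts were stimulation in wild type, stimulation in KO, KO minus wild type in medium, KO minus wild type after stimulation, and the difference between both stimulation responses. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes of a contrast, and a gene is called at an adjusted p below 0.05. Errors given with ± are standard errors of this fit, with 2 arrays per group. A gene not well above background on any array of a group has only a bound there. Its fold is given as at least N-fold, from the mean of the brighter group against, on each array of the dimmer group, the higher of the lowest signal well above background and the probe's own signal.

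Of 29 gene lists, 28 had at least 5 measured genes and were tested with limma's camera at a preset correlation between genes of 0.01, with p adjusted over the lists of a contrast. Of the sex-linked list only 1 gene was measured, and it was not tested. With the correlation between genes estimated from the residuals, no list passed in any contrast. That estimate had 4 residual degrees of freedom, and even the T cell cytokines on stimulation in wild type, with a median of 3.31, did not pass (camera, adjusted p = 0.271). Failing this alternative therefore cannot tell large list shifts from small ones. The estimated correlation lay between -0.08 (stromal and endothelial markers) and 0.97 (erythroid and platelet markers). It was 0.44 for the activation transcription factors and 0.47 for the T cell cytokines. Where it exceeds the preset 0.01, camera's p at the preset value can be too small. The test fry asks whether the genes of a list move on balance in 1 direction, and was an alternative. It called 12 and 9 lists for stimulation in wild type and KO, and 0 in each other contrast. Second lists of 17 granulocyte precursor, 25 B cell and 18 natural killer cell genes, each free of the genes of the first list of its own cell type, served to weigh other cell types. Of their genes 14, 25 and 17 were well above background on all 4 WT arrays, and 0, 2 and 5 stood in another list.

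The groups, contrasts, gene lists, tests, alternatives and the rule for named genes were choices made before the data were examined. By that rule the text names Lsp1, then the 8 largest log2 fold changes in each direction among called genes whose groups do not overlap, leaving out clone names, predicted genes and genes with only a bound. Up to 4 bounds per direction follow, largest first. Where a contrast has fewer than 8 calls in a direction, all are named. For each described list, the 2 to 4 members with the smallest p are named whether or not they pass. Which lists are described in a contrast, and how many members within that range, was settled after the values were seen. A few genes that this rule takes are not reported here, so that some lists have fewer named, and they remain in the counts and list tests.

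The alternatives were normexp background correction with an offset of 50, quantile, median and cyclic loess normalization, the deposited value table, no filter and a filter on all arrays, the mean of a gene's probes and each probe by itself, outlier spots kept, a trended and robust variance, a fit of only the groups compared, a 2-fold threshold, the replicate number as a block, each array left out in turn, an estimated correlation, and fry. The normexp alternative used the median signal and the median background, with the median in place of the mean signal. Leaving out both KO replicate 2 arrays, a block within genotype and a crossed block were added after seeing the data.

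The test was checked on simulated data with 15114 genes, 200 of them changed in the stimulated KO group, in 5 runs. Each simulated gene had the same spread in all 4 groups and independent noise on each array. The real arrays differ, with a spread of 0.431 and 0.454 in KO medium and stimulated KO against 0.253 and 0.250 in wild type. The rates below therefore need not hold for the KO comparisons. It recovered 0% of genes changed by 0.5 on the log2 scale, 24.5% of those changed by 1 and 73.9% of those changed by 2, with 3.6 false calls per run.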

Results

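The study measured messenger RNA in T cells from the spleens of wild-type (WT) mice and of mice lacking Lsp1 (KO). Lsp1 encodes leukocyte-specific protein 1, an F-actin-binding protein of white blood cells, and the series concerns its part in T cell migration in rheumatoid arthritis. Cells were in medium or stimulated for 6 h with antibodies against CD3 and CD28, which engage the T cell receptor and its costimulatory receptor. Each of the 4 groups had 2 arrays, and 15138 genes were tested. The labels do not say that the 2 arrays of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. An exact permutation test of 2 arrays against 2 can reach at smallest p = 0.333, so genes were tested with limma, which shares the spread over genes and groups. The spread between the 2 arrays of a group (root mean square SD over genes, log2) was 0.253 in WT medium, 0.250 in stimulated WT, 0.431 in KO medium and 0.454 in stimulated KO cells.

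Lsp1 itself was lower on every KO array than on every WT array. Its normalized log2 signal was 7.48 and 7.24 in WT medium, 7.06 and 6.99 in stimulated WT, 3.64 and 3.48 in KO medium, and 3.69 and 3.65 in stimulated KO cells. KO minus WT was -3.79 ± 0.13 in medium (13.9-fold lower, adjusted p = 0.00127) and -3.35 ± 0.13 after stimulation (10.2-fold lower, adjusted p = 0.00268). The single Lsp1 probe stayed well above background on all 4 KO arrays. The labels do not say which part of the gene is deleted, so that remaining signal cannot be assigned to a part of the transcript. Without WT stimulated replicate 2 the stimulated difference was -3.39 with an adjusted p of 0.0602. Fitting only the groups compared gave adjusted p of 0.0690 in medium and 0.0753 after stimulation, and without both KO replicate 2 arrays they were 0.170 and 0.0704.

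**Figure D1:**
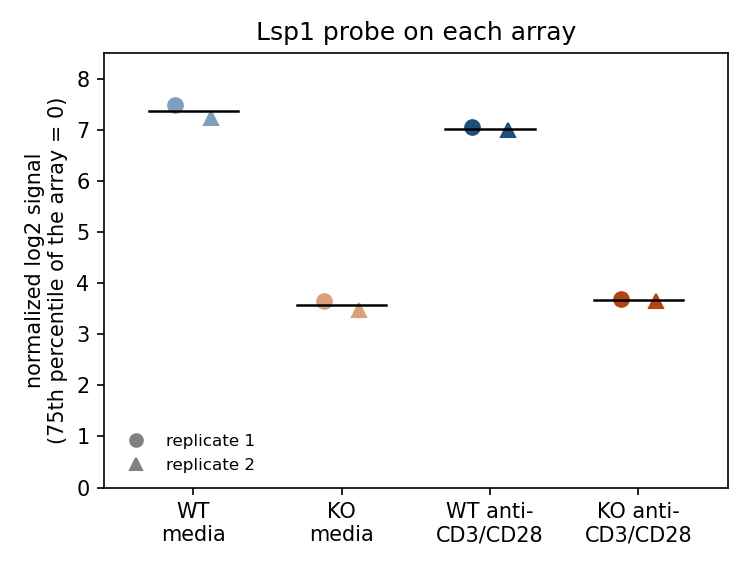
Normalized log2 signal of the Lsp1 probe on each of the 8 arrays (75th percentile of the array set to 0), with a line at the mean of each group. The KO arrays lie between 3.48 and 3.69 and the WT arrays between 6.99 and 7.48.

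The response of WT cells to anti-CD3/CD28 came next. Cytokine and chemokine genes were among the largest increases. Il13, a type 2 cytokine, rose by 7.74 ± 0.51 on the log2 scale (adjusted p = 0.00120), Csf2, which encodes GM-CSF, by 6.66 ± 0.24 (adjusted p = 0.000284), Il2, the T cell growth factor, by 5.86 ± 0.32 (adjusted p = 0.000606) and Ifng by 5.25 ± 0.53 (adjusted p = 0.00489). The chemokine genes Ccl17 (5.83 ± 0.45), Cxcl9 (5.55 ± 1.04) and Ccl4 (4.82 ± 0.32) rose with them, as did the serine protease inhibitor gene Serpina3f (5.12 ± 0.54). Ccl1 was at least 303-fold higher, Il17a at least 30.4-fold, Idi2 at least 13.0-fold and Egr4 at least 12.1-fold, each against medium arrays where it was not well above background. Decreases among the largest were those of Rab7b, a small GTPase gene (-2.82 ± 0.46), Lrrc75b (-2.46 ± 0.44), the fatty acid elongase gene Elovl7 (-2.19 ± 0.20), Prr7 (-2.10 ± 0.36), Tdrp (-2.05 ± 0.39), Mup20 (-2.04 ± 0.34) and Serp2 (-2.03 ± 0.24). Klhl14 was at least 4.31-fold lower, P2ry6 at least 4.30-fold, Clec4a4 at least 3.39-fold and Mycl at least 2.71-fold.

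In all, 1553 genes were called in WT cells, 972 higher and 581 lower, and 779 of them changed at least 2-fold. At an unadjusted p below 0.05 there were 4470 genes, against 756.9 from chance alone. The median of all genes shifted by -0.09. The count fell to 212 without WT medium replicate 1, 616 without replicate 2, 199 without WT stimulated replicate 1 and 231 without replicate 2. It was 3003 with no filter on dim probes and 2713 in a fit of the WT arrays alone, 1287 higher and 1426 lower. With a replicate block within genotype, added after seeing the data, it was 3518, 1462 higher and 2056 lower, so the share of increases depended on the fit.

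**Figure D2:**
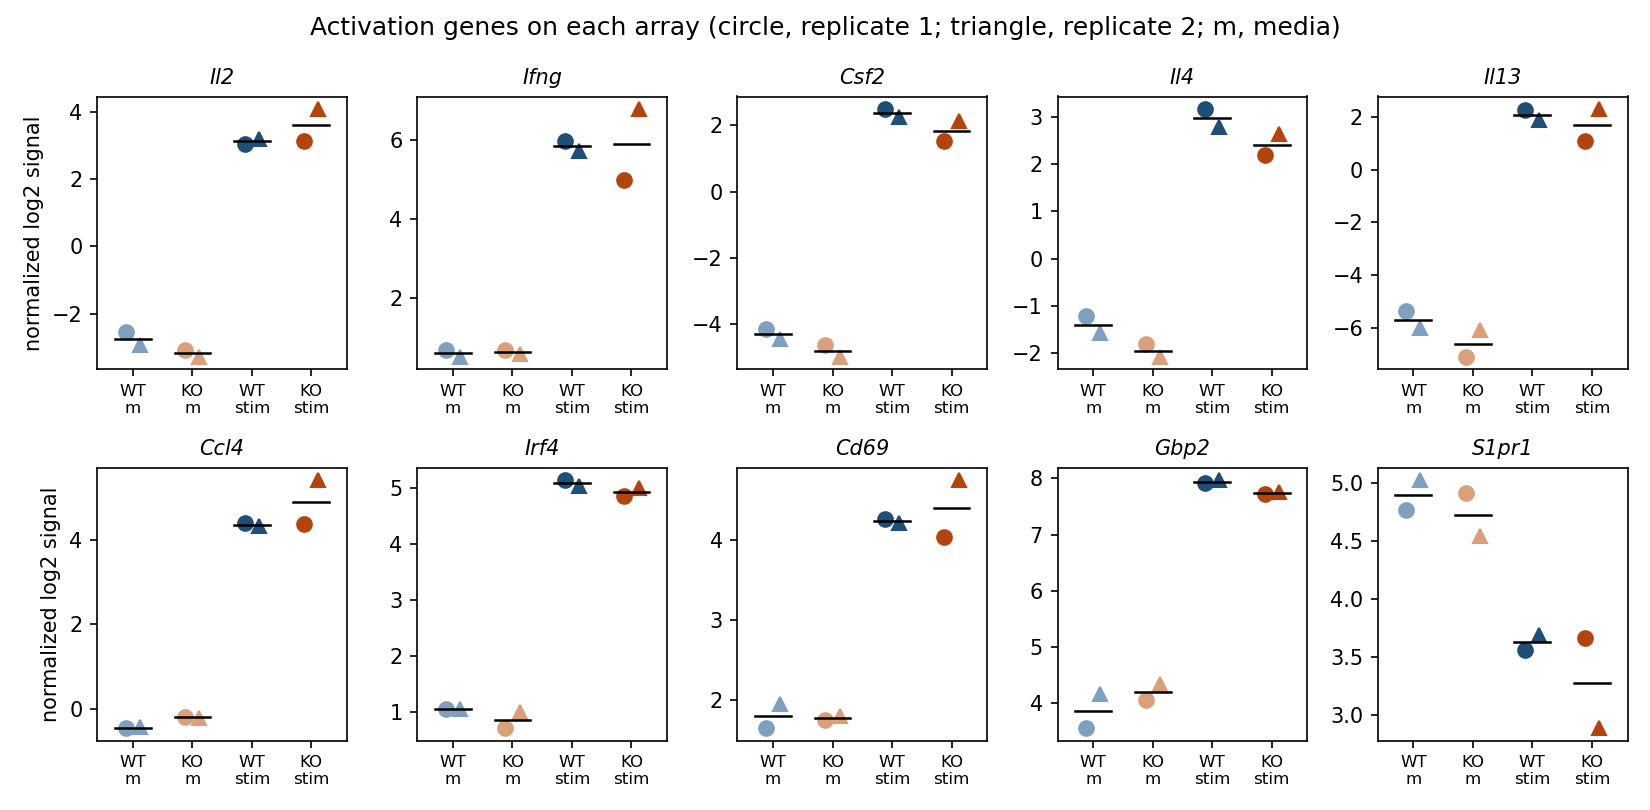
Normalized log2 signal of 10 genes on each of the 8 arrays, by group and replicate. Csf2, Il2, Ifng and Ccl4 lie higher on every stimulated array than on any medium array of the same genotype, and S1pr1 lies lower.

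Genes of early activation rose together in WT cells. Of 30 immediate early and activation-induced transcription factors 21 rose and none fell, and 24 rose when adjusted over the list alone. Irf4 rose by 4.02 ± 0.14, Myc by 3.79 ± 0.26 and Egr1 by 3.17 ± 0.23. Among 23 activation surface markers 14 rose (17 adjusted over the list alone), including Il2ra, a chain of the interleukin-2 receptor (3.36 ± 0.24), Tnfsf14 (3.11 ± 0.23) and Cd274, which encodes PD-L1 (2.88 ± 0.15). Of 21 T cell cytokines 14 rose (18 adjusted over the list alone), among them Csf2 and Il4 (4.38 ± 0.23). Of 14 measured chemokines 9 rose, with the same number adjusted over the list alone, among them Ccl4, Ccl22 (4.16 ± 0.27) and Xcl1 (3.62 ± 0.27). The list medians were 1.29, 0.92, 3.31 and 3.75, and camera called all 4 lists (adjusted p = 9.38e-19, 2.23e-12, 9.91e-17 and 1.37e-08). With an estimated correlation the adjusted p was 0.271 for the transcription factors, surface markers and cytokines and 0.287 for the chemokines.

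Interferon-stimulated genes also rose in WT cells, 23 of 28 with none falling (24 adjusted over the list alone), among them Gbp2 (4.08 ± 0.22), Oasl2 (3.68 ± 0.20) and Zbp1 (2.93 ± 0.16). The list median was 1.68 and camera called it (adjusted p = 6.78e-22, and adjusted p = 0.271 with an estimated correlation). Ribosome biogenesis genes rose in 23 of 27 cases, the same count as when adjusted over the list alone, with a median of 1.16. Polr1b, a subunit of RNA polymerase I, rose by 1.83 ± 0.17 and Tsr1 by 1.48 ± 0.13 (list adjusted p = 1.4e-18, and adjusted p = 0.274 with an estimated correlation). Of 24 regulators of helper and regulatory lineages 11 rose and 1 fell (12 and 1 adjusted over the list alone), and the cytokine signalling inhibitors Socs1 (3.24 ± 0.18) and Cish (3.03 ± 0.17) were among the increases. Of 22 apoptosis regulators 5 rose and none fell (13 and 4 adjusted over the list alone), with the survival genes Bcl2 at 2.27 ± 0.19 and Bcl2l1 at 2.01 ± 0.20. Camera called the lineage and apoptosis lists (adjusted p = 1.31e-06 and 0.000369), with adjusted p = 0.274 and 0.271 with an estimated correlation.

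Genes tied to migration were examined because of the question of the series. Chemokine and homing receptors moved both ways in WT cells: of 21, 3 rose and 3 fell (5 and 5 adjusted over the list alone). Ccr4 rose by 2.30 ± 0.24 and Ccr8 by 1.72 ± 0.24, while Cxcr1 fell by 1.56 ± 0.22 and Cxcr3, a receptor for Cxcl9, fell by 0.87 ± 0.17. Of 22 integrins and adhesion molecules 2 rose, Itgb3 (1.44 ± 0.16) and Icam1 (1.29 ± 0.18), and none fell, also when adjusted over the list alone. Of 45 actin cytoskeleton and motility genes, Lcp1, which encodes L-plastin, rose by 0.85 ± 0.13 and Flna, which encodes filamin A, fell by 0.64 ± 0.14, and only 1 rose and 0 fell when adjusted over the list alone. Camera called none of these 3 lists (adjusted p = 0.997, 0.735 and 0.997). Naive and quiescence genes had a median of -0.68, with 4 of 23 falling and 1 rising (13 and 2 adjusted over the list alone). S1pr1, the receptor for exit from lymphoid tissue, fell by 1.27 ± 0.28, Tob1 fell by 1.50 ± 0.29 and Dapl1 fell by 1.30 ± 0.29, while Ly6c1 rose by 1.52 ± 0.19 (list adjusted p = 0.00287, and adjusted p = 0.734 with an estimated correlation). Of 29 genes of the ERK pathway and its feedback 7 rose (8 adjusted over the list alone), including the kinase gene Map3k8 (1.90 ± 0.27) and the feedback inhibitor gene Spry1 (1.63 ± 0.21). That list was called with a median of 0.07 (adjusted p = 0.0131, and adjusted p = 0.594 with an estimated correlation).

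KO cells stimulated in the same way gave a response of like composition. Il2 rose by 6.79 ± 0.32 (adjusted p = 0.000550), Csf2 by 6.65 ± 0.24 (adjusted p = 0.000402) and Ifng by 5.26 ± 0.53 (adjusted p = 0.00491). Cxcl9 rose by 6.28 ± 1.04, Ccl17 by 5.96 ± 0.45, the ubiquitin-like modifier gene Ubd by 5.33 ± 0.64, Ccl4 by 5.11 ± 0.32 and the carbonic anhydrase gene Car12 by 5.06 ± 0.21. Il13 was at least 217-fold higher, Ccl1 at least 166-fold, Il17a at least 40.0-fold and Lif at least 27.5-fold. Decreases among the largest were those of Rab7b (-3.16 ± 0.46), Thbd, which encodes thrombomodulin (-2.25 ± 0.21), Lrrc75b (-2.25 ± 0.44), Elovl7 (-1.88 ± 0.20), Serp2 (-1.88 ± 0.24), Tdrp (-1.86 ± 0.39) and Atp6v0d2 (-1.82 ± 0.24). P2ry6 was at least 5.99-fold lower, Clec4a4 at least 4.27-fold, Hpgd at least 3.57-fold and Mycl at least 3.30-fold.

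There were 1230 calls in KO cells, 886 higher and 344 lower, with 689 changed at least 2-fold and 3844 at an unadjusted p below 0.05. The median of all genes shifted by -0.08. The count was 777 without WT medium replicate 1 and as many without replicate 2, 580 without KO medium replicate 1, 366 without KO medium replicate 2, 585 without WT stimulated replicate 1 and as many without replicate 2, and 497 without KO stimulated replicate 2. It was 38 in a fit of the KO arrays alone, 37 higher and 1 lower. With a replicate block within genotype, added after seeing the data, it was 2768, 1351 higher and 1417 lower. The share of increases thus depended on the fit here too.

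By group, 22 of 30 activation transcription factors rose in KO cells (27 adjusted over the list alone), with Irf4 at 4.07 ± 0.14, Egr1 at 3.87 ± 0.23 and Nr4a1 at 3.33 ± 0.21. Of the surface markers 12 of 23 rose (17 adjusted over the list alone), with Il2ra at 4.03 ± 0.24 and Cd274 at 2.78 ± 0.15. Of the cytokines 16 of 21 rose (18 adjusted over the list alone), among them Csf2 and Il2, and of the chemokines 9 of 14 (9, with 1 falling, adjusted over the list alone), among them Ccl4 and Xcl1 (4.36 ± 0.27). Interferon-stimulated genes rose in 22 of 28 cases (26 adjusted over the list alone), with Gbp2 at 3.54 ± 0.22 and Oasl2 at 3.14 ± 0.20. Camera called these 5 lists (adjusted p = 1.1e-23, 2.79e-13, 1.72e-19, 1.13e-08 and 1.1e-23). With an estimated correlation the adjusted p was 0.355 for the chemokines and 0.196 for the other 4 lists. The cytokine median lay 2.51 above the KO medium mean on KO stimulated replicate 1 and 4.57 on replicate 2, against 3.35 and 3.27 on the WT stimulated arrays relative to WT medium. Neutrophil markers, which were higher on the KO replicate 2 arrays, are given with the genotype comparisons.

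Ribosome biogenesis genes rose in 24 of 27 cases in KO cells, also when adjusted over the list alone, with Nolc1 at 1.93 ± 0.17 and Tsr1 at 1.52 ± 0.13. Of the lineage regulators 11 of 24 rose and none fell (11 and 2 adjusted over the list alone), with Cish at 3.33 ± 0.17 and Socs1 at 3.05 ± 0.18. Of the apoptosis regulators 8 of 22 rose (11, with 1 falling, adjusted over the list alone), with Bcl2l1 at 2.38 ± 0.20 and Bcl2 at 2.19 ± 0.19. Camera called these 3 lists (adjusted p = 4.43e-23, 4.71e-08 and 8.45e-06), with adjusted p = 0.242, 0.242 and 0.196 with an estimated correlation. Naive and quiescence genes fell in 4 of 23 cases and 1 rose (13 and 2 adjusted over the list alone). Tob1 fell by 1.53 ± 0.29 and S1pr1 by 1.44 ± 0.28, while Ly6c1 rose by 1.11 ± 0.19 (list adjusted p = 0.000192, and adjusted p = 0.586 with an estimated correlation). ERK pathway genes rose in 9 of 29 cases (10, with 1 falling, adjusted over the list alone), including Spry1 (1.86 ± 0.21) and Dusp4 (1.05 ± 0.13), and the list was called (adjusted p = 0.00726, and adjusted p = 0.565 with an estimated correlation). Of the homing receptors 2 of 21 rose, Ccr4 (2.37 ± 0.24) and Ccr8 (1.92 ± 0.24), and 2 fell (5 and 6 adjusted over the list alone). Of the integrins 2 of 22 rose, Itgb3 (1.27 ± 0.16) and Icam1 (1.30 ± 0.18), also when adjusted over the list alone, and the list median was -0.02 with a mean of 0.03. Of the 45 actin and motility genes Lcp1 rose by 0.60 ± 0.13, none passed when adjusted over the list alone, and Ezr, which encodes ezrin, stood at -0.63 ± 0.16 without passing (adjusted p = 0.0690). Camera called none of these last 3 lists (adjusted p = 0.750, 0.709 and 0.515).

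The responses of both genotypes were then compared gene by gene. Of the genes called, 995 were called in both genotypes, all in the same direction: 736 rose in both, where independent lists would share 56.9, and 259 fell in both, where they would share 13.2. Both comparisons share 1 estimate of spread per gene, which the values for independent lists leave out, so these are only a rough reference. Of the 558 genes called in WT alone 529 had the same sign in KO, and of the 235 called in KO alone 226 had the same sign in WT. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.819 and Spearman rho = 0.748, with a total least squares slope of 0.957 for KO on WT. From single arrays r lay between 0.463 and 0.804 over 16 pairings.

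**Figure D3:**
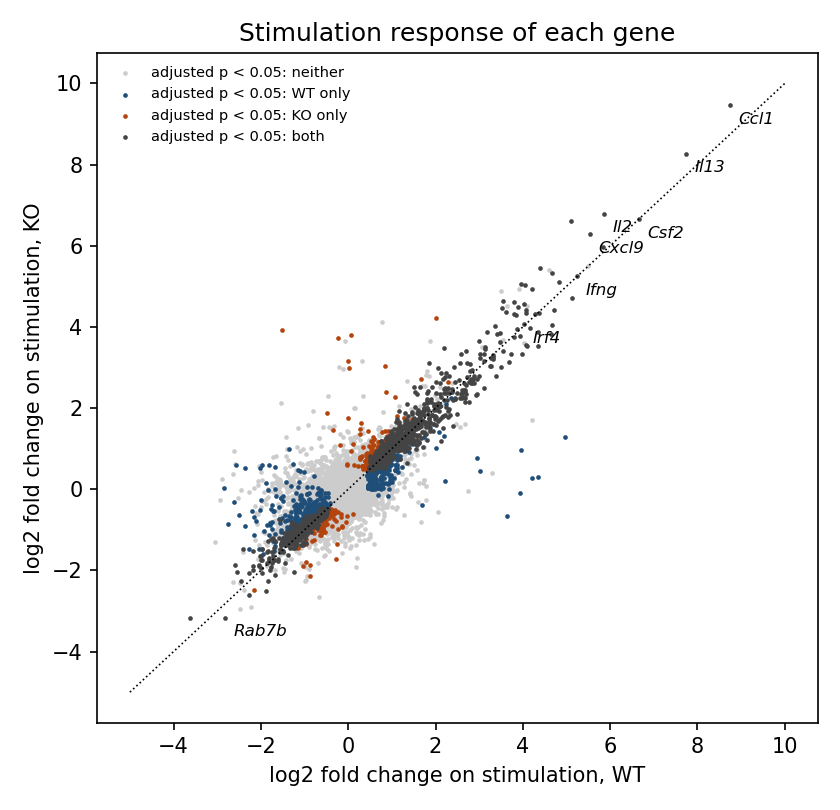
Log2 fold change on stimulation in WT (x axis) and KO (y axis) cells, 1 point per gene for 15138 genes. The 995 genes called in both genotypes all lie in the quadrants of equal sign.

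In medium, loss of Lsp1 came with a call for 1 gene, Lsp1 itself. Interferon-stimulated genes lay higher in KO cells, with positive values for 27 of 28 and a median of 0.46. Ifit3 was at 0.98 ± 0.17 (adjusted p = 0.527), Ifit1 at 1.06 ± 0.24 and Oasl2 at 0.85 ± 0.20 (adjusted p = 0.704 for both) and Usp18 at 0.72 ± 0.18 (adjusted p = 0.736). No member passed over all genes and 3 passed as higher adjusted over the list alone. B cell markers lay lower, negative for 16 of 17 with a median of -0.52, among them Blk (-0.75 ± 0.14, adjusted p = 0.558), Ms4a1, which encodes CD20 (-1.15 ± 0.25, adjusted p = 0.617), and Fcmr (-0.86 ± 0.21, adjusted p = 0.736). None passed over all genes and 8 passed as lower adjusted over the list alone. Natural killer cell markers were negative for 12 of 15 with a median of -0.49, with Klri2 at -0.63 ± 0.13 (adjusted p = 0.594), Klrb1c at -0.70 ± 0.18, Klra8 at -0.64 ± 0.21 and Klra9 at -0.39 ± 0.13 (adjusted p = 0.736 for these 3), and 1 passed as lower adjusted over the list alone. Camera called the 3 lists (adjusted p = 5.69e-14, 8.82e-09 and 0.000117), and with an estimated correlation the adjusted p was 0.630 for each. Fry called 0 lists in this comparison.

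Markers of other blood cells differed between the KO medium arrays. Against the WT mean, the median of the neutrophil markers was -0.42 on KO replicate 1 and 3.83 on replicate 2, that of the erythroid and platelet markers -0.49 and 1.76, that of the monocyte and macrophage markers 0.06 and 0.96, and that of the cell cycle genes 0.03 and 0.74. On the same arrays the interferon-stimulated genes had medians of 0.50 and 0.51, the B cell markers -0.56 and -0.62, and the natural killer cell markers -0.36 and -0.42. Of these lists 12 of 15 neutrophil, 15 of 16 erythroid and platelet and 15 of 16 monocyte and macrophage markers were also well above background on all 4 WT arrays, as were 16 of 17 B cell and 15 of 15 natural killer cell markers. Of the natural killer cell markers 4 also stood in another list, and of each of the others 1. Over both arrays the neutrophil list had a median of 1.77, with Elane, neutrophil elastase, at 2.11 ± 1.29, Mpo, myeloperoxidase, at 1.77 ± 1.28, Hdc at 1.41 ± 0.86 and Csf3r at -0.40 ± 0.25. Monocyte markers had a median of 0.54 (Lyz2 1.76 ± 1.14, Cd14 1.15 ± 0.79, Cd300e 0.53 ± 0.28), erythroid and platelet markers 0.70 (Ppbp 1.04 ± 0.78, Gp9 0.80 ± 0.86) and cell cycle genes 0.39 (Aurkb 1.003 ± 0.59, Tyms 0.30 ± 0.14). No member of these 4 lists passed, over all genes or adjusted over the list alone. Camera called them (adjusted p = 0.0111, 0.00353, 0.0153 and 0.000726), and with an estimated correlation the adjusted p was 0.916 for each. Without KO medium replicate 2 the neutrophil median was -0.42, the erythroid -0.49, the monocyte 0.06 and the cell cycle 0.03, none called. Without both KO replicate 2 arrays the erythroid list was called as lower in KO (median -0.49, adjusted p = 0.0109).

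For migration and signalling genes in medium, the medians of the receptor, integrin, actin, ERK and transcription factor lists were -0.05, -0.11, -0.08, -0.14 and -0.15, and none of the 5 was called. Against the WT mean they were, in this order, 0.02, 0.01, 0.03, 0.007 and -0.06 on KO medium replicate 1. On replicate 2, where markers of other blood cells were high, they were -0.17, -0.23, -0.16, -0.15 and -0.18. Among homing receptors Ccr6 was at -0.53 ± 0.15. Itgb1 stood at 0.38 ± 0.18, Cd226 at -0.48 ± 0.25, Diaph1, an actin-nucleating formin gene, at -0.65 ± 0.26 and Rdx, which encodes radixin, at -0.26 ± 0.11. The ERK feedback genes Spry2 and Dusp6 were at -0.69 ± 0.22 and -0.45 ± 0.19, and the transcription factor gene Hif1a at 0.48 ± 0.18. None of these genes passed, also when adjusted over their lists alone. The adjusted p of these lists, in the same order, was 0.880, 0.882, 0.809, 0.513 and 0.286. Glycolysis genes were positive for 15 of 20 (median 0.12, Slc16a3 0.72 ± 0.23, Eno1 0.42 ± 0.20) and common reference transcripts had a median of 0.11 (Gapdh 0.25 ± 0.13, Ywhaz 0.28 ± 0.15), with no member passing over all genes or adjusted over the list alone. Both lists were called (adjusted p = 0.00164 and 0.0163), and with an estimated correlation the adjusted p was 0.630 for both. Of 47 genes near Lsp1 none passed over all genes, Ccnd1 standing at -1.27 ± 0.19 (adjusted p = 0.343), Tnnt3 at -1.16 ± 0.18 (adjusted p = 0.349) and Dusp8 at 0.85 ± 0.27, and 2 passed as lower adjusted over the list alone (list adjusted p = 0.619).

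At an unadjusted p below 0.05 the medium comparison held 865 genes, against 756.9 from chance alone. The count of calls was 2 without KO medium replicate 1. Camera called 9 lists here, 4 without WT medium replicate 2 and 4 without KO medium replicate 2.

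After stimulation, 3 genes were lower in KO cells: Lsp1, Olfr325 and Gpr39. Olfr325, an olfactory receptor gene, was at least 2.48-fold lower (adjusted p = 0.00496) and Gpr39, which encodes a zinc-sensing receptor, at least 2.49-fold lower (adjusted p = 0.0102). Both were well above background only on the WT stimulated arrays, at normalized log2 signals of -4.40 and -4.53 for Olfr325 and -4.34 and -4.57 for Gpr39. With normexp background correction neither passed (adjusted p = 0.338 for both), nor with a trended and robust variance (adjusted p = 0.166 for both). The comparison held 762 genes at an unadjusted p below 0.05, against 756.9 from chance alone. The count of calls was 5 (2 higher, 3 lower) without KO medium replicate 1 or 2, 5 (all lower) without WT stimulated replicate 1, 13 (10 higher, 3 lower) without KO stimulated replicate 1, 0 without WT stimulated replicate 2, 2 (both lower) without WT medium replicate 1 or 2, and 2 (1 higher, 1 lower) without KO stimulated replicate 2. It was 0 without both KO replicate 2 arrays.

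B cell markers again lay lower in KO cells, negative for 16 of 17 with a median of -0.58, and 10 passed as lower adjusted over the list alone. Fcmr was at -1.15 ± 0.21 (adjusted p = 0.363), Blk at -0.73 ± 0.14 (adjusted p = 0.398) and Cd79b at -0.71 ± 0.12 (adjusted p = 0.337). Natural killer cell markers were negative for 13 of 15 with a median of -0.43, with Klri2 at -0.62 ± 0.13 (adjusted p = 0.398), Klrb1c at -0.72 ± 0.18, Klra9 at -0.46 ± 0.13 and Klrb1b at -0.46 ± 0.15, and 1 passed as lower adjusted over the list alone. Interferon-stimulated genes were positive for 24 of 28 with a median of 0.39, with Ifit3 at 0.75 ± 0.17 (adjusted p = 0.488), Ifit1 at 0.86 ± 0.24, Ifit2 at 0.42 ± 0.14 and Dhx58 at 0.66 ± 0.24, and 0 passed adjusted over the list alone. Camera called the 3 lists (adjusted p = 1.07e-11, 5.88e-05 and 6.58e-09), and with an estimated correlation the adjusted p was 0.828 for each. Fry called 0 lists in this comparison. Against the WT mean, the interferon-stimulated median was 0.14 on KO stimulated replicate 1 and 0.60 on replicate 2, the B cell median -0.71 and -0.66, and the natural killer cell median -0.35 and -0.41.

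The markers of other blood cells were again high on 1 KO array. The neutrophil median was -0.27 on KO stimulated replicate 1 and 3.31 on replicate 2, the erythroid and platelet median -0.49 and 2.02, the monocyte and macrophage median 0.11 and 1.16, and the cell cycle median -0.07 and 0.65. Over both arrays the neutrophil list had a median of 1.37 (Mpo 1.78 ± 1.28, Il1b 1.30 ± 0.59), the monocyte list 0.56 (Cd300e 0.57 ± 0.28, C1qa 0.55 ± 0.28), the erythroid list 0.81 (Gp9 0.86 ± 0.86, Gp1bb 0.31 ± 0.25) and the cell cycle list 0.26 (Mki67 0.78 ± 0.51, Ccne1 0.38 ± 0.25). No member passed, over all genes or adjusted over the list alone. Camera called these 4 lists (adjusted p = 0.0084, 0.000772, 0.00493 and 0.00276), and with an estimated correlation the adjusted p was 0.828 for each.

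Activation genes differed between the same KO arrays. The cytokine median was -0.13 on KO stimulated replicate 1 and 0.55 on replicate 2, that of the activation transcription factors -0.08 and 0.38, that of the surface markers -0.02 and 0.24, that of the ribosome biogenesis genes -0.09 and 0.28, and that of the naive genes 0.01 and -0.54, against the WT mean. Over both arrays cytokines had a median of 0.26 (Il21 1.49 ± 0.51, Il4 -0.57 ± 0.23, Csf2 -0.54 ± 0.24), surface markers 0.16 (Tnfsf11 0.61 ± 0.22, Pdcd1 0.60 ± 0.24, Lag3 0.45 ± 0.18), transcription factors 0.15 (Nr4a2 0.46 ± 0.21, Bhlhe40 0.35 ± 0.15), ribosome biogenesis 0.10 (Polr1a 0.23 ± 0.18, Utp20 0.22 ± 0.13) and naive genes -0.21 (Txnip -0.42 ± 0.21). No member passed, over all genes or adjusted over the list alone. Camera called these 5 lists (adjusted p = 0.0254, 0.00514, 0.00514, 0.0113 and 0.00644), and with an estimated correlation the adjusted p was 0.828 for each. Without KO stimulated replicate 2 the cytokine, transcription factor, ribosome, naive, cell cycle, neutrophil and erythroid medians took the opposite sign. The cytokine list was then called as lower in KO (median -0.13, adjusted p = 0.0334), also without both KO replicate 2 arrays (adjusted p = 0.0300), where the erythroid list was called as lower too (median -0.49, adjusted p = 0.0129). Without KO stimulated replicate 2, 6 lists were called in place of 12, against 7 without WT stimulated replicate 2.

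Migration genes after stimulation gave no call. Among them Cxcr6 stood at -0.63 ± 0.28, Itgb3 at -0.38 ± 0.16 and Itgb1 at 0.38 ± 0.18, with list adjusted p of 0.822 for the receptors and 0.901 for the integrins. Actin and motility genes were negative for 36 of 45 with a median of -0.10 (adjusted p = 0.0532). Against the WT mean the median was -0.05 on KO stimulated replicate 1 and -0.16 on replicate 2, with the WT arrays at -0.03 and 0.03. Among the actin genes Rdx stood at -0.23 ± 0.11 and Arpc5, a subunit of the Arp2/3 complex, at -0.19 ± 0.10. None of these genes passed, also when adjusted over the lists alone. Near Lsp1, Ccnd1 was at -1.06 ± 0.19 (adjusted p = 0.344) and Dusp8 at 0.78 ± 0.27, with 0 of 47 passing and a list adjusted p of 0.471.

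**Figure D4:**
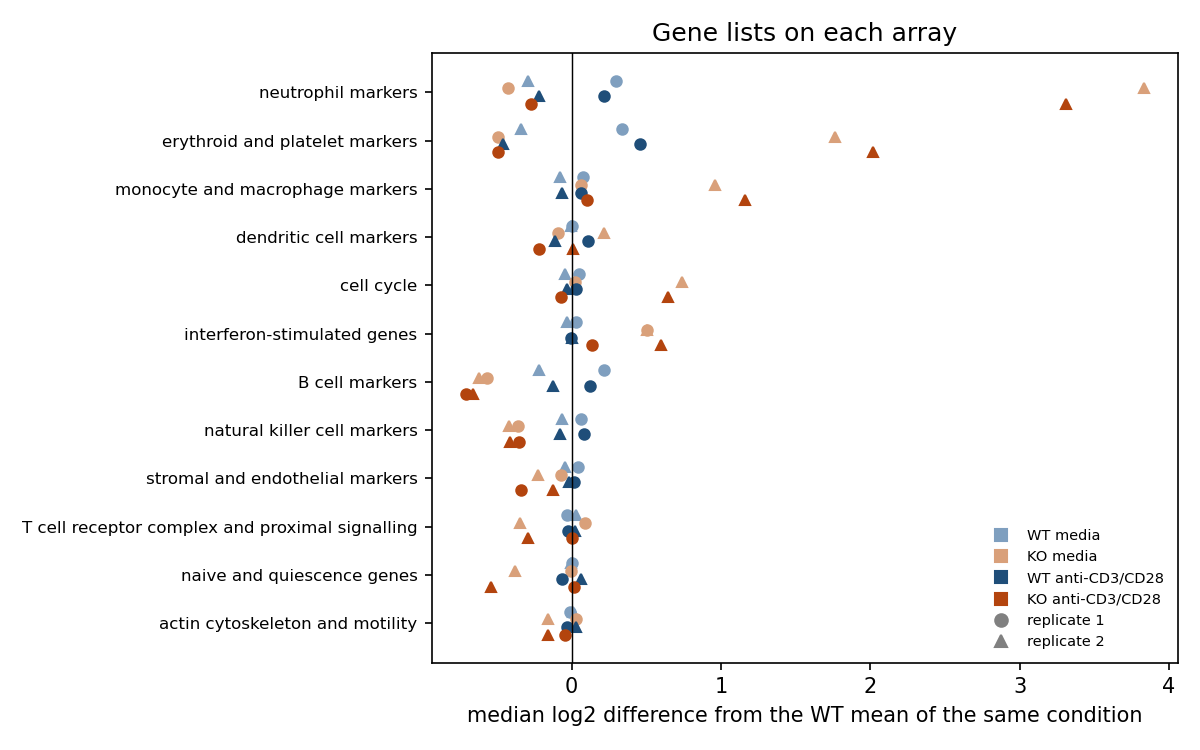
Median log2 difference from the WT mean of the same condition for 12 gene lists (y axis), 1 point per array, coloured by group and shaped by replicate. Neutrophil markers reach 3.83 and 3.31 on the KO replicate 2 arrays, while B cell markers lie between -0.71 and -0.56 on all 4 KO arrays.

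The difference between the stimulation responses of KO and WT cells was tested directly. Olfr325 was the 1 gene called (adjusted p = 0.0422), but it was well above background only on the WT stimulated arrays, so no size is given for it. In all, 459 genes had an unadjusted p below 0.05, against 756.9 from chance alone. Il2 differed by 0.93 ± 0.45 and Lta by 0.57 ± 0.28, none passing, and the cytokine list was not called (median 0.26, adjusted p = 0.0538). The activation transcription factors were positive for 25 of 30 (median 0.28), with Nr4a1 at 0.74 ± 0.30, Egr2 at 0.72 ± 0.31 and Nr4a2 at 0.63 ± 0.29, and ribosome biogenesis genes for 26 of 27 (median 0.16), with Polr1a at 0.51 ± 0.25, Nop58 at 0.50 ± 0.30 and Utp20 at 0.43 ± 0.18. Glycolysis genes were negative for 14 of 20 (median -0.11, Eno1 -0.62 ± 0.28, Slc16a1 -0.38 ± 0.18) and common reference transcripts for 12 of 15 (median -0.15, B2m -0.35 ± 0.15, Eef1a1 -0.27 ± 0.14). No member of any of these lists passed, over all genes or adjusted over the list alone. Camera called the transcription factor, ribosome, glycolysis and reference lists (adjusted p = 0.00162, 0.00208, 0.0341 and 0.0117), and with an estimated correlation the adjusted p was 0.964 for each. Fry called 0 lists for the difference. Interferon-stimulated genes were not called (median -0.09, adjusted p = 0.0675), with Zbp1 at -0.61 ± 0.23, Oasl2 at -0.54 ± 0.28 and Rtp4 at -0.52 ± 0.27.

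Of the 8 fits with 1 array left out, 7 called no gene for this difference, and without WT stimulated replicate 1 there was 1 call but Olfr325 did not pass (adjusted p = 0.198). Camera called 7 lists without WT medium replicate 1, 1 without WT medium replicate 2, 11 without KO medium replicate 1, 13 without KO medium replicate 2, 12 without KO stimulated replicate 1 and 10 without KO stimulated replicate 2, against 4 with all arrays. Without KO stimulated replicate 2 neither the transcription factors (median 0.07, adjusted p = 0.906) nor the ribosome genes (adjusted p = 0.982) were called, and neither was called without WT medium replicate 2 (adjusted p = 0.118 and 0.102). The glycolysis list passed in 8 of 19 alternatives, with medians from -0.23 to -0.05. It was not called without WT medium replicate 1, WT stimulated replicate 2, KO medium replicate 2 or KO stimulated replicate 1 (adjusted p = 0.417, 0.116, 0.171 and 0.166). The reference list passed in 12 of 19 and was not called without WT medium replicate 2 or KO stimulated replicate 1 (adjusted p = 0.0528 and 0.183).

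Calls for Lsp1 loss in medium and after stimulation shared 1 gene, Lsp1. At an unadjusted p below 0.05 in both, 109 genes were higher in KO and 82 lower, where independent lists would share 10.4 and 11.2. These comparisons were not independent: the replicate differences of the KO medium and stimulated arrays correlated at 0.742 across genes, which the values for independent lists leave out, so the excess over them is no measure of shared genotype differences.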

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

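Of the tests in this part, the correlation of replicate differences, Lsp1 on the KO replicate 2 arrays, the B cell and interferon-stimulated medians on KO replicate 1, the permutation test and the second lists without members that other blood cells express were chosen only after the result was seen, while the 3 second gene lists were written down before their values were. The weighing of KO replicate 1 beside the criteria of the second B cell and natural killer cell lists was not written down before.

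The difference between the stimulation responses (KO minus WT) passed its own test for Olfr325 (limma, adjusted p = 0.0422), a probe well above background only on the WT stimulated arrays, so that its size was not measured. Among gene lists the difference was called for the activation transcription factors (median 0.28), ribosome biogenesis (0.16), glycolysis (-0.11) and the common reference transcripts (-0.15), each not called with an estimated correlation. Without KO stimulated replicate 2 the transcription factor median was 0.07 (adjusted p = 0.906) and that of ribosome biogenesis 0.0098 (adjusted p = 0.982), and without KO stimulated replicate 1 the glycolysis and reference lists were not called (adjusted p = 0.166 and 0.183). Among probes not named here, which no comparison used, 12 were well above background on all 4 stimulated arrays and no medium array, and 232 on all 4 medium arrays and no stimulated array. A further 3 were so on all 4 KO arrays and no WT array, and 7 the other way round.

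The highest values of any marker list were those of granulocyte, erythroid and monocyte genes on both KO replicate 2 arrays. Replicate 2 minus replicate 1 in KO, in medium and after stimulation, was 5.41 and 5.75 for S100a9 (which reached 7.18 and 6.36), 3.18 and 3.21 for Hba-a1 (7.05 and 7.13) and 3.02 and 2.55 for Lyz2 (1.35 and 0.74), but -0.42 and -0.34 for Csf3r (6.76 and 6.63). The replicate differences of the medium and stimulated KO arrays correlated at 0.742 across genes, against 0.161 in WT, which argues against noise of a single array, and Lsp1 on the higher of these arrays lay at -3.33 against the lowest WT array, which argues against a swapped genotype label. A second list of 17 granulocyte precursor genes had a median for replicate 2 minus replicate 1 of 3.49 in medium and 2.40 after stimulation. Cells of these types in the samples of both replicate 2 arrays are thus a candidate explanation. Against the WT mean, the median of the T cell receptor and proximal signalling genes was 0.09 in medium and 0.004 after stimulation on KO replicate 1. On both replicate 2 arrays it was lower, at -0.34 and -0.29. The labels do not say that these arrays share a preparation. How T cells were separated is not given in the sources used here, and a difference in the biology of those samples stays untested.

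The medians of the B cell and natural killer cell markers were lower on all 4 KO arrays than on the WT arrays. On KO replicate 1 this was not particular to them. The neutrophil medians (-0.42 in medium and -0.27 after stimulation) and the erythroid and platelet medians (-0.49 and -0.49) also lay below both WT arrays there. The monocyte and macrophage medians (0.06 and 0.11) did not. On KO replicate 1, with low granulocyte markers, the B cell median was -0.56 in medium and -0.71 after stimulation, with Ms4a1 at -1.14 and -1.06 and Cd79b at -0.30 and -0.75, which argues against dilution by the other cells of KO replicate 2 as the source. A second list of 25 B cell genes had medians of -0.38 and -0.42 on KO replicate 1 but 0.13 and 0.19 on replicate 2, and a second list of 18 natural killer cell genes had -0.24 and -0.20 on replicate 1 and -0.48 and 0.19 on replicate 2. A median above 0 had been set beforehand as counting against fewer such cells, and it was met only on replicate 2. There 15 of 25 B cell genes lay above 0 on each array. Cd24a, Fcgr2b, Btk and Syk, which other blood cells express, were left out after the values were seen. The B cell medians there were then 0.0038 and 0.059, inside the WT spread but still above 0, so the B cell criterion did not rest on these genes alone. Whether other blood cells also express further members of the list was not tested. The member Cd83 also stood in the list of activation surface markers. Without Tyrobp, Fcer1g and Car2 the natural killer cell medians were -0.53 and -0.17. With 10 of 18 natural killer cell genes above 0 and 8 below on the stimulated replicate 2 array, that median decides nothing. By the rule set beforehand, the medians above 0 on replicate 2 count against fewer B cells and fewer natural killer cells. On replicate 1 both second lists lay below both WT arrays. Weighing replicate 1 as well was not part of that rule. With it, the second lists do not decide. Fewer B or natural killer cells in the KO preparations and an effect of the genotype stay open.

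The list of interferon-stimulated genes had positive medians in KO, with 0 of 28 members passing over all genes in either condition and the call lost with an estimated correlation (adjusted p = 0.630 and 0.828). In medium the median was 0.50 on KO replicate 1 and 0.51 on replicate 2, which argues against the other cell types of replicate 2 as the source. After stimulation it was 0.14 on replicate 1 and 0.60 on replicate 2, so there the other cells and the genotype cannot be told apart, because replicate 1 lies above both WT arrays but far below replicate 2. An exact permutation test of the list mean in medium gave p = 0.333, the smallest that 2 arrays against 2 can give, so chance spread between preparations stays open. An effect of Lsp1 loss on these genes may be proposed only as a hypothesis.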

How the results depend on the processing

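Leaving out both KO replicate 2 arrays, the replicate block within genotype and the crossed block were chosen only after the data were seen, and other alternatives before. Over all alternatives, 5168 of 5586 values of named genes kept direction and side of the threshold, 402 no longer passed, 10 newly passed and 6 reversed. For stimulation 1572 of 1744 were kept in WT and 1298 of 1504 in KO. For Lsp1 loss they were 916 of 918 in medium and 964 of 986 after stimulation, and 418 of 434 for the difference. Most named genes of these last 3 comparisons did not pass in the main fit, so being kept says little about their size. Elane in medium ranged from 0.39 to 3.83. Of 931 values of gene lists 772 were kept, 138 were no longer called and 21 reversed. Unless a sentence shows it, the cause was not tested. With normexp or the deposited value table, genes called for Lsp1 loss after stimulation were 1 and for the difference between responses 0, and a filter on all arrays, which leaves out Olfr325 and Gpr39 as dim on some arrays, gave the same counts. The difference between responses had 3 calls with quantile normalization, 2 with median centring and 2 with cyclic loess, with 2 lists called under quantile normalization and 2 under cyclic loess. In these 3 scalings Lsp1 loss after stimulation had 4 calls, 1 higher and 3 lower, against 0 and 3. Median centring moved the median of all genes for stimulation in WT from -0.09 to 0.02 and that for the difference from 0.02 to -0.09. With no filter on dim probes, stimulation in WT had 3003 calls (2323 higher, 680 lower, against 972 and 581), the difference 0, the correlation of responses was 0.695, and lists called were 4 in medium and 2 for the difference. Each probe by itself gave 3 calls in medium, 8 after stimulation and 0 for the difference, and a trended and robust variance 0 for the difference. In a fit of only the groups compared, with fewer arrays, stimulation gave 2713 calls in WT (1287 higher, 1426 lower) and 38 in KO (37 and 1), Lsp1 loss gave 0 and 0, and Lsp1 stayed at -3.79 and -3.35 without passing. A 2-fold threshold left 779 and 689 calls. With an estimated correlation 0 lists were called in all 5 contrasts, and fry called 12 lists for stimulation in WT, 9 in KO, and 0 for both genotype comparisons and for the difference.

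Without each array in turn, calls ranged from 199 to 1753 for stimulation in WT, 366 to 1482 in KO, 1 to 2 for Lsp1 loss in medium, 0 to 13 after stimulation, 0 to 1 for the difference and 0 to 1 for the overlap of Lsp1 loss calls. Lsp1 lay between -3.92 and -3.67 in medium and between -3.39 and -3.32 after stimulation, and the correlation of responses between 0.698 and 0.843. Lists called ranged from 13 to 14, 11 to 15, 4 to 12, 6 to 17 and 1 to 13 in the 5 contrasts. A lone array left in a group was assumed to vary like the other groups. Without KO medium replicate 2, Gp9 was at -0.10, and the medians were 0.064 for monocyte (direction of the test), -0.42 for neutrophil and -0.49 for erythroid markers. Without KO stimulated replicate 2, Gp9 was at -0.24 and Ccne1 at -0.0040, and the medians were -0.077 for activation transcription factors, -0.13 for cytokines, 0.014 for naive genes, -0.088 for ribosome biogenesis, -0.070 for cell cycle, -0.27 for neutrophil and -0.49 for erythroid markers, with ribosome biogenesis at 0.0098 for the difference (direction of the test). At the other end of these ranges, without the KO replicate 1 array of the same condition, the values were 1.70 for Gp9, 0.96 for monocyte, 3.83 for neutrophil and 1.76 for erythroid markers in medium. After stimulation they were 1.96 for Gp9, 0.76 for Ccne1, 0.38 for activation transcription factors, 0.55 for cytokines, -0.54 for naive genes, 0.28 for ribosome biogenesis, 0.65 for cell cycle, 3.31 for neutrophil and 2.02 for erythroid markers, and 0.36 for ribosome biogenesis in the difference. Without both KO replicate 2 arrays the values were those without the 1 array of the condition, except -0.06 for ribosome biogenesis in the difference. The cytokine list was called in the opposite direction in both fits (adjusted p = 0.0334 and 0.0300), and erythroid markers without both arrays (adjusted p = 0.0109 in medium and 0.0129 after stimulation). That fit gave 2713 and 436 calls for stimulation, 0, 0 and 0 for both genotype comparisons and the difference, 0 for the overlap, 2 lists for the difference, and Lsp1 at -3.71 and -3.33 without passing.

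Arrays of the same number did not deviate together across genotypes: replicate differences correlated at -0.061 between genotypes in medium and -0.244 after stimulation. The numbers were therefore not taken as pairs across genotypes. Within a genotype, medium against stimulated, they correlated at 0.742 in KO and 0.161 in WT. No label ties a number to an animal, so the main fit used no block and left the KO difference between numbers in its spread. With the replicate number as a block, calls were 1559 and 1148 for stimulation, 2 for Lsp1 loss after stimulation and 0 for the difference. A replicate block within genotype gave 3518 (1462 higher, 2056 lower), 2768 (1351 and 1417) and 0. The crossed replicate block gave 5 for Lsp1 loss after stimulation. A slide or scan block was not run, since there was 1 slide and 1 scan. Signal over background limits the bounds, and genes not well above background on any array of 1 of the groups compared numbered 132 of the WT and 71 of the KO stimulation calls, with 6 more in KO so in both groups.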

Other observations

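The comparison of the Lsp1 neighbours with random lists, the correlation between differently numbered KO arrays and the naming of shared genotype genes were chosen only after the result was seen. The test of KO replicate 1 on the shared genes was written down before.

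Some metabolic genes rose on stimulation. In WT cells 4 of 22 cholesterol synthesis genes rose (8 adjusted over the list alone), among them Cyp51 (1.43 ± 0.26) and Hsd17b7 (1.13 ± 0.22), and in KO cells 3 rose (6 adjusted over the list alone), with Hsd17b7 at 1.22 ± 0.22 and Idi1 at 1.49 ± 0.32. Camera called that list in both (adjusted p = 1.22e-05 and 5.81e-06), with adjusted p = 0.518 and 0.565 with an estimated correlation. Of 20 glycolysis genes 4 rose and 2 fell in WT (8 and 3 adjusted over the list alone), with the phosphofructokinase genes Pfkp at 0.84 ± 0.11 and Pfkm at 0.68 ± 0.10 (list adjusted p = 0.00318, and adjusted p = 0.274 with an estimated correlation). In KO 2 glycolysis genes rose and the list was not called (adjusted p = 0.110), and the median difference between the genotypes' responses was -0.11. Of 18 heat shock and unfolded protein genes 4 rose and 2 fell in WT and 3 rose and 2 fell in KO. The chaperone gene Hsph1 rose by 0.93 ± 0.10 and 0.99 ± 0.10, Hspd1 rose by 1.29 ± 0.20 in KO, and Trib3 fell by 1.67 ± 0.21 in WT (list adjusted p = 0.684 and 0.528). Cell cycle genes were not called (adjusted p = 0.217 and 0.330), yet Ccnd2, a cyclin of the first growth phase, rose by 2.09 ± 0.19 in WT and 2.34 ± 0.19 in KO, and Cdk4 rose by 0.60 ± 0.13 in WT and stood at 0.56 ± 0.13 in KO (adjusted p = 0.0536). In WT the cell cycle median was -0.04 and the mean 0.16. Common reference transcripts had a median of 0.23 in WT (adjusted p = 0.00467, and adjusted p = 0.274 with an estimated correlation) and 0.05 in KO (adjusted p = 0.381).

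Of 28 T cell receptor and proximal signalling genes 3 rose in each genotype, among them Ptpn6, which encodes the phosphatase SHP-1 (1.37 ± 0.14 in WT, 1.31 ± 0.14 in KO), and Lcp2, which encodes the adaptor SLP-76 (0.87 ± 0.15 and 0.96 ± 0.15), and the list was not called (adjusted p = 0.217 and 0.381). Of 14 cytotoxic effector genes 5 rose and 1 fell in WT, with Cst7 at 1.71 ± 0.18 and Klrd1 at -1.74 ± 0.24, and 4 rose and 1 fell in KO, with Gzmc at 2.51 ± 0.29 (list adjusted p = 0.0789 and 0.214). Of 15 natural killer cell markers 4 rose and 3 fell in WT and 3 rose and 2 fell in KO. The ones that rose include Eomes (1.78 ± 0.14 and 1.53 ± 0.14) and Gzma (0.95 ± 0.13 and 1.17 ± 0.13), genes that activated T cells also express, and the list median of -0.36 in WT stood beside a mean of 0.13 (adjusted p = 0.986 and 0.955). Among 17 B cell markers Fcer2a rose by 1.52 ± 0.25 and Fcrla fell by 1.07 ± 0.18 in WT, while in KO 1 rose and 3 fell, with Cd79b at -0.78 ± 0.12 and Fcrla at -1.02 ± 0.18 (list adjusted p = 0.225 and 0.149). Camera called no other cell type list on stimulation: the adjusted p in WT and KO was 0.165 and 0.528 for dendritic cells, 0.835 and 0.709 for monocytes and macrophages, 0.835 and 0.709 for neutrophils, 0.927 and 0.721 for erythroid cells and platelets, and 0.621 and 0.330 for stromal and endothelial cells.

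Genes next to Lsp1 were examined for the hypothesis that a region kept around a targeted gene on backcrossing moves its neighbours. The mean size of the genotype difference over 47 neighbours, averaged over both conditions, was 0.244, at percentile 96.6 among 10000 random lists of like expression, whose median was 0.180. The neighbours that moved most were Ccnd1 (-1.16), Ascl2 (1.15), Ifitm2 (0.89), Ifitm1 (0.83), Dusp8 (0.82) and Tnnt3 (-0.75). Such a region may contribute, but no neighbour passed over all genes. Ifitm1 and Ifitm2 are also interferon-induced, Ifitm3 (0.62) is of the same family, and Irf7 (0.41) stood in the list of interferon-stimulated genes. The mean without these genes was not tested, so the percentile cannot tell such a region from the shift of interferon-stimulated genes.

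Genotype differences shared by medium and stimulated cells held 190 genes besides Lsp1 at an unadjusted p below 0.05 in both, 109 higher and 81 lower. The ones named here were chosen after their values were seen: Eaf2 (1.45 in medium, adjusted p = 0.312, and 1.77 after stimulation, adjusted p = 0.0947) and Aif1l (-3.27 and -2.62). KO replicate 1 lay beyond both WT arrays in 100% of the 190 genes, against 23.7% of the others, which decides nothing because the genes were chosen for that pattern. Across all genes, KO minus WT correlated at 0.501 between medium and stimulated cells from group means, at 0.296 from KO replicate 1 and 0.681 from KO replicate 2. Between differently numbered KO arrays it was 0.031 and 0.015, so on net their differences from WT were unrelated. The medians of the neutrophil and erythroid markers lay below the WT mean on KO replicate 1 and above it on replicate 2. Such opposite shifts can hide differences that the KO arrays share, so these values do not decide how much common differences add to that correlation.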
